A study of Homo sapiens with 16 samples.

How the data were processed

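RNA from 16 samples of MCF-7 cells was measured, 4 each of control, starvation, tamoxifen and combined treatment. Per the labels, cells were plated in medium with 10% fetal bovine serum and glucose at 1 g/L, then kept in that medium or moved to 1% serum and glucose at 0.5 g/L. A day later they were given tamoxifen at 5 µM or vehicle, and RNA was taken after 24 hours. The labels do not state whether the starvation medium stayed on during those 24 hours. RNA was labelled with 1 dye, Cy3, and hybridised to Agilent 4x44K human arrays, 4 to a slide, on 4 slides. Groups, replicate numbers and doses were taken from the labels, and slides and positions from the scan names.

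The authors deposited 2 kinds of file. The scanner files hold spot intensity in arbitrary units, made by the authors with Agilent Feature Extraction 10.7.3.1. Per the file headers, the deposited processed signal is an intensity from which background had been subtracted and spatial and multiplicative trends removed within each array, with surrogates for dim spots and no normalization between arrays. The deposited mean, median and local background signals are raw intensity values, and the deposited flags, a unit of the kind other, mark with 0 or 1 whether a spot was well above background, saturated or uneven. The deposited value table holds log2 values that the authors had normalized between arrays, since its columns share nearly 1 distribution, with medians from 7.235 to 7.256. The labels name limma for that step but give no version, background correction or offset. Over all spots and arrays the table lay nearest to the median signal after normexp correction with an offset of 16 and quantile normalization, with a median absolute difference of 0.0602 log2 units. Its identifiers were checked to be the spot numbers of the scanner files.

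The comparisons started from the processed signal of the scanner files. Of 44495 spots 43118 were no controls, and they hold 34127 probes. Probes were named through their accession in the RefSeq table (26377), their symbol (2223) or an older symbol (342), 576 kept the name in the file and 4609 had none. Uneven spots and spots that differed from their replicates were left out, no spot was saturated, and spots of 1 probe were averaged on the log2 scale. Each array's 75th percentile over non-control spots was subtracted. A probe was kept if it was well above background on all 4 arrays of at least 1 group, which left 19950 probes. A gene was read from its kept probe with the highest mean signal, which gave 15529 genes, of which 14057 had names and 1472 were unnamed probes. Probe coordinates are those of the files, on hg19. Depth in the sense of counts does not exist for arrays: the 75th percentile of intensity ran from 578.9 to 1489, and the number of arrays limits the precision.

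A model with 1 mean per group was fitted to all 16 arrays in limma 3.58.1 under R 4.3.3, with the data.table package (version 1.17.8), followed by empirical Bayes moderation. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the genes of a comparison, with a threshold of 0.05. There were 6 comparisons: starvation against control, tamoxifen against control, combined against control, combined against tamoxifen, combined against starvation, and the interaction, which is the tamoxifen effect in starved cells minus that in full medium. Errors of changes are moderated standard errors.

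The 27 gene lists were fixed before the data were examined. They cover ER targets, DNA replication, mitosis, cell cycle inhibitors, cholesterol synthesis, fatty acid synthesis, LXR targets, glycolysis, hypoxia, respiration, fatty acid oxidation, ATF4 targets, ER stress, heat shock, FOXO targets, MAPK and early genes, lysosome, p53 targets, ribosome biogenesis, interferon, NF-kB, NRF2, AHR, apoptosis, luminal genes, basal genes and markers of other cell types. Some genes stand in several lists, and NDUFA4 and AKR1C2 have no probe. Members without a kept probe were left out too, and counts are out of those measured. These were 9 for NF-kB, 7 for basal genes and 5 for markers of other cell types, each fewer than listed. A gene dim in 1 group is kept if another group holds it above background. Members near background can thus enter through the group in which they are high. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the 27 lists of a comparison. Of 64 calls 19 held with an estimated correlation, and those are named where the lists are described. The fry test, which asks whether a list's genes moved, on balance, 1 way and compares them with no other genes, was run beside it: it kept 52 of the 64 calls, 1 of the 7 for the interaction among them, lost 12 and gained 18. For these tests 101 missing values in 100 genes took their group's mean. In every comparison the lists whose median, mean and test differed in sign were among those that did not pass: 4 for starvation against control, 2 for combined against control, 4 for combined against tamoxifen, 7 for combined against starvation and 3 for the interaction.

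Genes named in the text followed a rule fixed before the data were examined. It allows up to 12 of the largest rises and 12 of the largest falls among called genes with a symbol and no overlap between the groups' arrays. It further allows up to 4 members of each list described, those with the lowest adjusted p. It always allows ESR1, PGR, TFF1, GREB1, CCND1, MYC, E2F1, CDKN1A, CDKN1B, PTEN, EGR1, IGF1R, INSR, IRS1, IRS2, TXNIP, HMGCS1, LDLR, SCD and ASNS, which were fixed from biology and from knowledge of the study. A few further genes are named in the closing section and marked there as chosen after their values were seen.

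The method was tested on simulated data made from the spread of these arrays. Of 100 genes given a log2 change of 1 it recovered 42, and of 100 given 0.5 it recovered 10, with 1 unchanged gene called. In a second simulated comparison with no change it called 0 genes. Few of the simulated genes changed, and their noise was drawn independently, without the difference between starved replicates described below. These values therefore need not hold for the real comparisons. Alternatives planned before the data were examined were other normalizations (quantile, array median), normexp correction with an offset of 50, the deposited table, no filter or a filter on all 16 arrays, the mean of a gene's probes, a trend with a robust prior, array weights, only the groups compared, blocks for replicate number, slide and position, slide as a random effect, leaving out each array in turn, and stricter thresholds. Alternatives added after the data were seen were a block for the number pairs (replicates 1 and 2 against 3 and 4), each number pair alone, and leaving out both dim combined arrays (1 and 4). Whether replicate numbers pair the samples across groups was checked: residuals of arrays with the same number correlated with a mean r of 0.038, and the best match of an array in another group had the same number in 13 of 48 cases, so the samples were treated as unpaired. No column of values was left out of the comparisons.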

Results

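RNA levels were measured on 16 one-colour arrays from MCF-7 cells, an oestrogen receptor positive human breast cancer line whose growth responds to oestradiol. The 16 arrays formed 4 groups of 4. Control cells had medium with glucose at 1 g/L and 10% fetal bovine serum, and starved cells had glucose at 0.5 g/L and 1% serum. The tamoxifen group had the full medium and 5 µM tamoxifen, a drug that competes with oestradiol for its receptor, for 24 hours. The combined group was moved to the starvation medium and then given the same dose of tamoxifen for 24 hours, during which the labels do not state the medium. The labels number the replicates of each group from 1 to 4 but do not say that they were separate cultures, so the p-values measure the spread between these samples, which could be technical in part.

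The 75th percentile of spot intensity, the nearest measure of depth in array data, lay between 578.9 in combined 4 and 1489 in tamoxifen 2. The share of spots well above background lay between 54.1% in combined 1 and 69.3% in combined 2. A total of 15529 genes were tested, and the number of arrays limits the precision of each value. Across genes, which are not independent replicates, arrays of 1 group correlated with r from 0.962 in the combined group to 0.994 in the tamoxifen group. Each group lay on at least 2 of the 4 slides, but no slide held both a starvation and a combined array. Starved arrays numbered 1 and 2 also differed from those numbered 3 and 4: in the starvation group 2209 genes differed between these number pairs, and in the combined group 2115. Between control arrays 0 genes differed with limma (680 at an unadjusted p under 0.05), and 1 did between tamoxifen arrays. Values within slides and within number pairs therefore stand beside some of the gene groups below, and for the lists that passed between 2 groups the medians with the sign of the whole comparison are counted. Those lists passed on the same arrays that the parts are taken from, so a shared sign is likely from the start. Such counts are a weak check. Gene levels are log2 intensities relative to the 75th percentile of their array, with the standard deviation over 4 arrays, and changes are differences of group means with their standard error.

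The first comparison, starvation against control, asked which genes respond to low glucose and serum. Of the DNA replication list 40 of 43 genes fell in starved cells, and 14 of 25 FOXO targets, which low insulin signalling raises, rose. Of the ATF4 targets, genes of the amino acid stress response, 20 of 33 rose, though that list did not pass with an estimated correlation (adjusted p = 0.201 with an estimated correlation). KLHL24, a member of the FOXO target list measured at chromosome 3, 183402052 to 183402111 of hg19, rose from -4.75 ± 0.24 in control to -1.84 ± 0.23 in starved cells, a change of 7.53-fold. CDC6, which loads the replicative helicase onto origins, was measured at chromosome 17, 38459354 to 38459413, and fell from -3.77 ± 0.22 to -6.13 ± 0.18 (adjusted p = 6.23e-06). It was above background on 1 of 4 starved arrays, and where 1 of 4 arrays of a group held a gene above background no fold is given here or below. NUPR1, a stress-induced regulator of transcription, rose 9.34-fold (log2 change 3.22 ± 0.29, adjusted p = 5.8e-06), and ATF3, a transcription factor of the stress response, rose 10.1-fold (3.34 ± 0.43, adjusted p = 8.33e-05). In total 3672 genes changed at an adjusted p under 0.05, which is 23.6% of those tested: 1885 rose and 1787 fell, and 1035 changed at least 2-fold. With slide as a block the count was 2632, and on the arrays numbered 1 and 2 alone it was 1281.

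The DNA replication and G1/S list, which holds licensing, fork, nucleotide supply and E2F-driven genes, fell with a median log2 change of -1.17 (adjusted p = 5.98e-25; 0.0454 with an estimated correlation). Of its 43 measured members 40 fell and 0 rose, and adjusted over the list alone 43 fell. GINS1, a subunit of the replicative helicase, had a log2 change of -1.41 ± 0.11, POLA2, a subunit of the primase complex, -1.64 ± 0.15, and RFC2, part of the clamp loader, -1.34 ± 0.14. E2F1, the transcription factor that drives many of these genes, fell 3.23-fold (-1.69 ± 0.24, adjusted p = 0.000194). The list's median was -1.29 and -1.19 on the 2 slides that hold both groups, -0.82 on the arrays numbered 1 and 2, and -1.55 on those numbered 3 and 4. The G2/M and mitosis list fell less, with a median of -0.55 (adjusted p = 2.17e-06; adjusted p = 0.313 with an estimated correlation). Of its 35 members 16 fell, also 16 adjusted over the list alone, among them BUB1B, a spindle checkpoint kinase, at -0.70 ± 0.15 and BIRC5, the chromosomal passenger survivin, at -0.72 ± 0.17. CCNB1, the mitotic cyclin B1, had a change of -0.87 ± 0.19 on its brightest probe (adjusted p = 0.00431) and of -0.26 over the mean of its probes (adjusted p = 0.112). The mitosis list's median was -0.17 on the arrays numbered 1 and 2 and -0.71 on those numbered 3 and 4. Of the 12 measured genes in the list of cell cycle inhibitors 4 rose and 3 fell, and the list did not pass the test (median 0.41, adjusted p = 0.0839, though 0.0321 without control 2 and 0.0372 without starvation 1). CDKN1A, the inhibitor p21, rose 1.77-fold (adjusted p = 0.00514), while CDKN1B, the inhibitor p27, had a log2 change of 0.24 ± 0.12 (adjusted p = 0.175).

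The list of ATF4 targets, which hold genes of amino acid supply and tRNA charging, rose with a median of 0.94 (adjusted p = 4.39e-09; adjusted p = 0.201 with an estimated correlation). Of its 33 members 20 rose and 0 fell, and adjusted over the list alone 22 rose. CEBPG, a partner of ATF4, rose 4.32-fold, SARS1, the seryl-tRNA synthetase, 1.99-fold, and ASNS, asparagine synthetase, 2.26-fold (adjusted p = 0.007). DDIT3, the stress factor CHOP, was measured at chromosome 12, 57911200 to 57911526, and rose from -2.40 ± 0.80 to 1.41 ± 1.85. Its log2 change was 5.33 on the arrays numbered 1 and 2 and 2.28 on those numbered 3 and 4. NIBAN1, a stress-induced gene at chromosome 1, 184760227 to 184760286, rose from -6.95 ± 0.53, with 1 of 4 control arrays above background, to -2.73 ± 1.86 (adjusted p = 0.00628; 0.0504 after normexp background correction). The list's median was 1.25 and 1.03 within the 2 slides, 1.10 on the arrays numbered 1 and 2, and 0.70 on those numbered 3 and 4. The ER stress list, made up of chaperones of the unfolded protein response, did not pass: 3 of 18 members rose and 2 fell, with a median of -0.26, a mean of 0.03 and an adjusted p of 0.869. The heat shock list of cytosolic chaperones fell with a median of -0.60 (adjusted p = 2.61e-05; 0.0454 with an estimated correlation): 8 of 14 members fell, or 10 adjusted over the list alone. They included DNAJA1 at -1.31 ± 0.19 and HSPA8, the constitutive HSP70, at -1.13 ± 0.26.

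FOXO targets, which are held down by insulin and PI3K signalling, rose with a median of 0.81 (adjusted p = 4.39e-09; 0.0454 with an estimated correlation), with medians of 0.69 and 0.76 within slides and of 0.39 and 1.11 within number pairs. Of 25 members 14 rose, or 16 adjusted over the list alone. Besides KLHL24 they included CCNG2, cyclin G2, at 1.78 ± 0.22, IRS2, an adaptor of the insulin receptor, at 1.15 ± 0.21, and FOXO3 itself at 1.01 ± 0.13. TXNIP, a glucose-induced inhibitor of glucose uptake at chromosome 1, 145442447 to 145442506, did not pass (-0.28 ± 0.78, adjusted p = 0.851). Its change was -1.87 on the arrays numbered 1 and 2 (adjusted p = 0.0303) and 1.32 on those numbered 3 and 4 (adjusted p = 0.00416). The p53 target list rose with a median of 0.66 (adjusted p = 4.86e-09; 0.000958 with an estimated correlation): 15 of 22 members rose, or 16 adjusted over the list alone. BBC3, the death activator PUMA, rose 4.04-fold, GDF15, a secreted stress cytokine, 2.84-fold, and BTG2, which restrains proliferation, 2.84-fold. The MAPK and early gene list rose with a median of 0.54 (adjusted p = 2.61e-05; adjusted p = 0.174 with an estimated correlation), with 11 of 26 members up, or 14 adjusted over the list alone. Its median was 0.40 on the arrays numbered 1 and 2 and 0.71 on those numbered 3 and 4. CCN2, a matricellular growth factor, rose 11.3-fold, MYC, a driver of growth, 2.05-fold (adjusted p = 0.000895), and JUN 1.90-fold, while EGR1, an early growth response factor, had a change of 0.56 ± 0.28 (adjusted p = 0.173, though 0.0404 with number pairs as a block, 0.0305 with only the groups compared and 0.0168 on the arrays numbered 3 and 4). The NF-kB list rose with a median of 0.88 (adjusted p = 0.00022; adjusted p = 0.174 with an estimated correlation): 5 of 9 members rose and 1 fell, or 6 and 1 adjusted over the list alone. TNF, the inflammatory cytokine, rose 4.16-fold, and TNFAIP3, a feedback inhibitor above background on 1 of 4 control arrays, rose from -6.19 ± 0.39 to -4.13 ± 0.12 (adjusted p = 0.00013). The list of apoptosis regulators rose with a median of 0.54 (adjusted p = 0.00947; 0.0454 with an estimated correlation), with 9 of 22 members up and 2 down, or 10 and 2 adjusted over the list alone. BIK, a death activator, was at 1.13 ± 0.17 and the death receptor TNFRSF10B at 0.99 ± 0.16.

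Part of the genes of glucose use (8 of 21), respiration (10 of 43) and sterol synthesis (5 of 23) fell in starved cells, and none of these 3 lists kept its call with an estimated correlation. The glycolysis list fell with a median of -0.27 (adjusted p = 0.00164; adjusted p = 0.197 with an estimated correlation): 8 of 21 members fell and 1 rose, or 9 and 1 adjusted over the list alone. LDHA, which makes lactate, had a change of -1.01 ± 0.12 and PKM, pyruvate kinase, -0.93 ± 0.16, while HK2, the hexokinase of fast-growing cells, rose by 0.84 ± 0.15. The list of the citric acid cycle and respiratory chain fell with a median of -0.33 (adjusted p = 2.57e-05; adjusted p = 0.197 with an estimated correlation), with 10 of 43 members down, also 10 adjusted over the list alone. NDUFB8 of complex I was at -0.61 ± 0.13 and SDHB of complex II at -0.56 ± 0.13. The cholesterol synthesis list fell with a median of -0.29 (adjusted p = 0.00754; adjusted p = 0.367 with an estimated correlation; 0.0843 without starvation 4), with 5 of 23 members down, also 5 adjusted over the list alone. ACAT2, which makes acetoacetyl-CoA, fell 2.97-fold and FDPS, farnesyl diphosphate synthase, 1.82-fold, while HMGCS1, HMG-CoA synthase, was at -0.35 ± 0.25 (adjusted p = 0.366). LDLR, the receptor for LDL, was at -0.23 ± 0.25 over all arrays (adjusted p = 0.562), but at 0.37 on those numbered 1 and 2 and at -0.83 on those numbered 3 and 4 (adjusted p = 0.00986), and these effects differed (adjusted p = 0.00935). The cholesterol list's median was -0.08 on the arrays numbered 1 and 2 and -0.63 on those numbered 3 and 4. All 24 list medians within slides and all 24 within number pairs had the sign of the whole comparison for the 12 lists that passed.

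The remaining lists did not pass in starved cells. ER targets, genes raised by oestradiol, had 6 members up and 9 down of 45 (median -0.14, adjusted p = 0.48). PGR, the progesterone receptor, was at -0.08 ± 0.22, GREB1, an oestrogen-driven growth gene, at -0.24 ± 0.30, TFF1, a secreted trefoil peptide, at -0.12 ± 0.15 and ESR1, the receptor itself, at 0.15 ± 0.11. Fatty acid synthesis had 2 of 18 members up and 7 down (median -0.22, adjusted p = 0.067, though 0.0458 without control 3, 0.0219 without starvation 1 and 0.0162 without starvation 2). Hypoxia genes had 4 of 17 up and 2 down (median 0.44, adjusted p = 0.128), NRF2 targets 4 of 19 up and 3 down (0.27, 0.256) and LXR targets 3 of 9 up (0.12, 0.213). Interferon genes had 3 of 20 up and 1 down (0.07, 0.414). Of genes of the lysosome 6 of 34 were up and 3 down (0.03, 0.328), and of ribosome biogenesis 4 of 29 down (-0.06, 0.26). Fatty acid oxidation had 1 of 18 up and 2 down (median 0.02 and mean 0.12 with a test direction of down, 0.939). The AHR list had 2 of 10 up (median -0.02, mean 0.17, adjusted p = 0.711), luminal genes 3 of 18 up and 1 down (0.10, 0.216), and basal genes 3 of 7 up (0.78, 0.109, though 0.0363 without control 2). Markers of other cell types, which a pure culture should lack, had 5 measured genes, of which 1 was up (-0.01, 0.841).

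**Figure D1:**
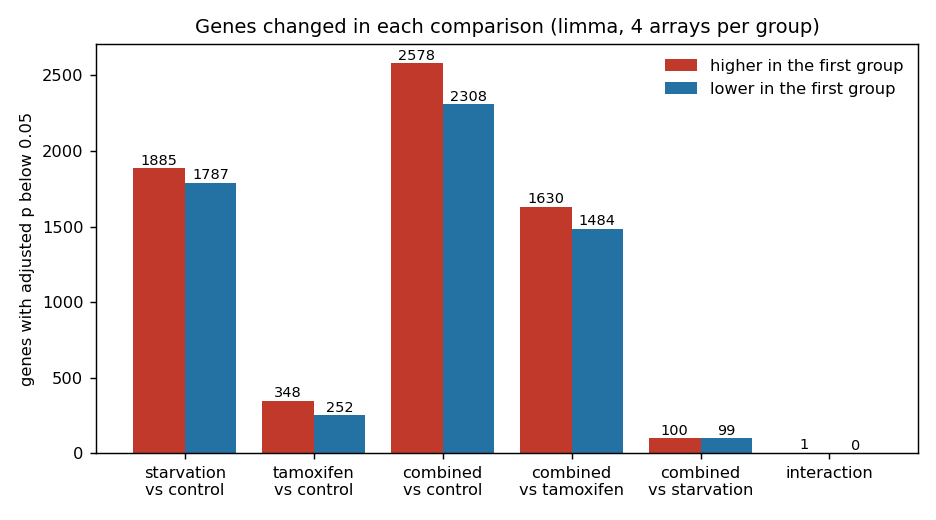
Number of genes that rose and fell in each comparison at an adjusted p under 0.05, of 15529 tested (bars from 0, number of genes on the axis). Starvation against control shows 3672 genes and tamoxifen against control 600.

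**Figure D2:**
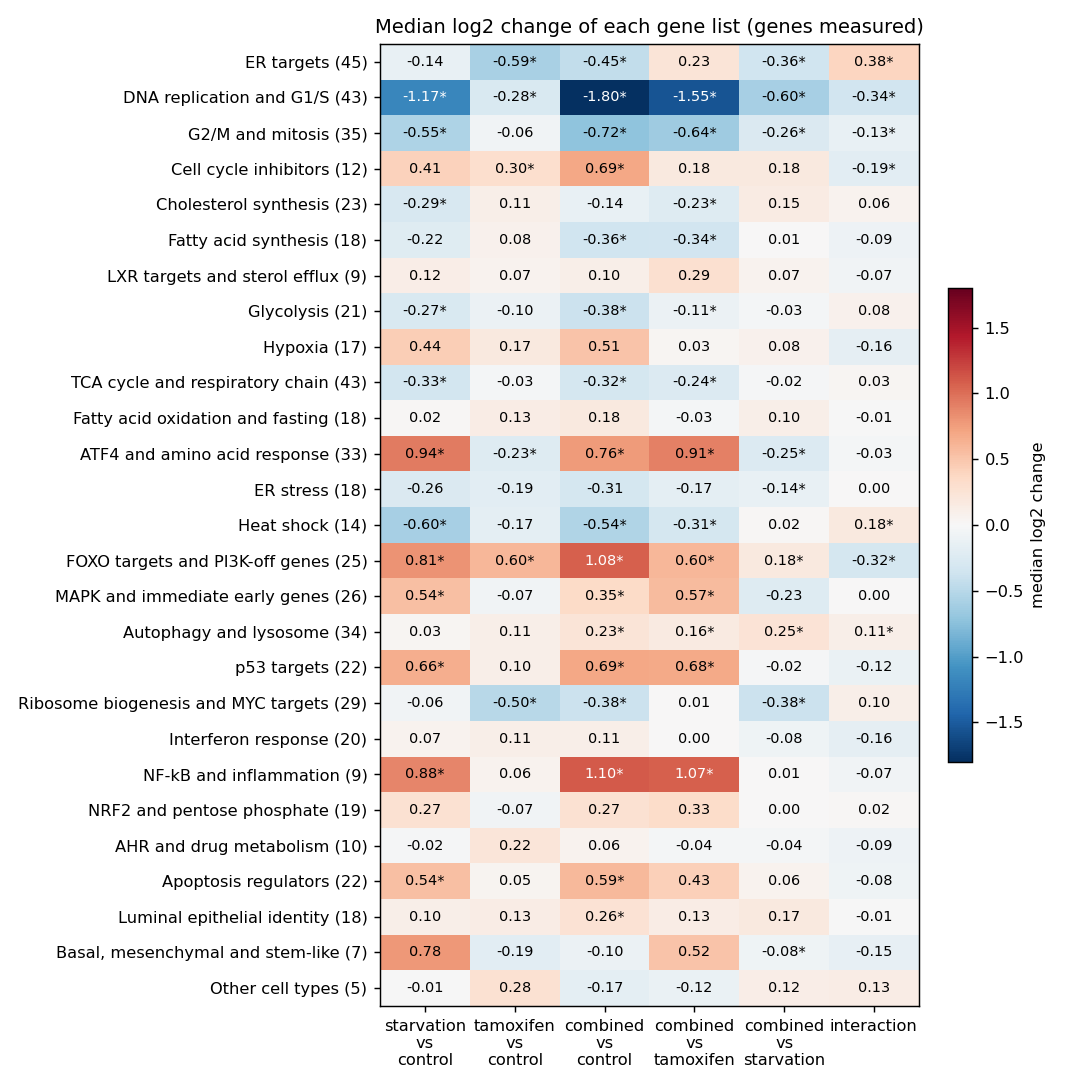
Median log2 change of each of the 27 gene lists in each comparison, with an asterisk where the list passed the test (adjusted p under 0.05; colour from blue for lower to red for higher). The DNA replication list stands at -1.17 with starvation, -0.28 with tamoxifen and -1.80 with both.

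Tamoxifen against control asked which genes respond to the drug in full medium, and oestrogen-induced genes were the group that fell furthest. PGR, measured at chromosome 11, 100900858 to 100900917, fell from -0.11 ± 0.23 to -2.22 ± 0.15, which is 4.31-fold (adjusted p = 9.09e-05). GREB1, at chromosome 2, 11721329 to 11721388, fell from 2.90 ± 0.22 to 0.49 ± 0.08, which is 5.30-fold (adjusted p = 0.000411). SGK3, a kinase downstream of PI3K, fell 4.73-fold, and CXCL12, a chemokine, 4.94-fold. The ER target list had 17 of 45 members down and 2 up, or 24 down and 2 up adjusted over the list alone, with a median of -0.59 (adjusted p = 8.66e-17; 6.93e-06 with an estimated correlation). Its median was -0.74, -0.44, -0.69 and -0.50 on the 4 slides, and -0.57 and -0.58 within the number pairs. TFF1 was at -0.48 ± 0.15 (adjusted p = 0.091) and CCND1, cyclin D1, at -0.54 ± 0.15 (adjusted p = 0.0614), and each passed under 5 alternatives. Their adjusted p there ran from 0.00462 with array weights to 0.0495 without both dim combined arrays for TFF1, and from 0.00306 with array weights to 0.0498 with number pairs as a block for CCND1. ESR1 was at 0.19 ± 0.11 (adjusted p = 0.439). EGR3, an early gene of the list that 3 of 4 tamoxifen arrays held above background, fell 5.84-fold. Outside the list, MGP, a matrix protein that binds calcium, fell 5.34-fold and RAMP3, a receptor partner protein, 5.85-fold. IL20, a cytokine, fell from -1.77 ± 0.50 to -6.24 ± 1.65, and was above background on 1 of 4 tamoxifen arrays (adjusted p = 0.000905).

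The highest rise with tamoxifen was in ATP4A, the stomach's proton pump subunit, measured at chromosome 19, 36041100 to 36041159: it was at -7.93 ± 0.39 in control and -2.42 ± 0.43 with tamoxifen, at least 14.3-fold higher (adjusted p = 7.14e-06). Such a bound is given where a group was above background on none of its arrays, and sets each of those arrays at its dimmest detected level. KRT13, a keratin of stratified epithelium above background on 1 of 4 control arrays, rose from -5.95 ± 0.60 to -3.52 ± 0.05 (adjusted p = 0.000494). PDE5A, which degrades cyclic GMP, rose 4.34-fold and UCA1, a long noncoding RNA, 5.78-fold. Genes of ribosome assembly and MYC-driven growth fell with a median of -0.50 (adjusted p = 8.85e-15; 0.000258 with an estimated correlation): 10 of 29 fell, or 17 adjusted over the list alone. MYBBP1A was at -0.75 ± 0.11, BOP1 at -0.82 ± 0.14 and RRP9 at -0.77 ± 0.11, all nucleolar proteins. MYC itself was at -0.18 ± 0.18 (adjusted p = 0.719). FOXO targets rose with a median of 0.60 (adjusted p = 1.22e-08; 0.0382 with an estimated correlation), with 5 of 25 up, or 12 adjusted over the list alone. KLHL24 was at 1.28 ± 0.17 (adjusted p = 0.000615) and CCNG2 at 1.27 ± 0.22 (adjusted p = 0.00462). Cell cycle inhibitors rose with a median of 0.30 (adjusted p = 0.00069; adjusted p = 0.103 with an estimated correlation), with 3 of 12 up, also 3 adjusted over the list alone, among them BTG2 at 0.93 ± 0.19. CDKN1A was at 0.15 ± 0.19 (adjusted p = 0.79). The DNA replication list had a median of -0.28 and passed (adjusted p = 1.58e-05; adjusted p = 0.476 with an estimated correlation) although 1 of 43 members fell and 0 did adjusted over the list alone (limma). E2F1 was at -0.55 ± 0.24 (adjusted p = 0.269, though 0.031 with array weights and 0.0226 with only the groups compared). ATF4 targets had a median of -0.23 with 0 of 33 members called, also 0 adjusted over the list alone (adjusted p = 0.0434; adjusted p = 0.728 with an estimated correlation). That call ended without control 1 (0.072), control 2 (0.147), tamoxifen 3 (0.136) or tamoxifen 4 (0.0911), and with slide as a block (0.0546).

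In all, 600 genes changed with tamoxifen, 348 up and 252 down, which is 3.86% of those tested, and 211 changed at least 2-fold. With slide as a block the count was 482, and on the arrays numbered 1 and 2 alone it was 5. It was 300 without tamoxifen 1, 302 without tamoxifen 2, 329 without tamoxifen 4, 310 without control 3 and 388 without control 4. All 24 slide medians and all 12 number-pair medians of the 6 lists that passed had the sign of the whole comparison. Cholesterol synthesis, which tamoxifen can touch through sterol enzymes, had 0 of 23 members called (limma), with a median of 0.11 (adjusted p = 0.285), HMGCS1 at 0.19 ± 0.25 and LDLR at 0.13 ± 0.25. Heat shock genes had a median of -0.17 and did not pass (adjusted p = 0.0554), but did without control 2 (0.00897) or tamoxifen 4 (0.0456). Basal genes had 2 of 7 members down and a median of -0.19 (adjusted p = 0.116, though 0.0329 without control 3).

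The combined treatment against control asked what starvation and tamoxifen did together, and it changed more genes than either treatment alone: 4886, of which 2578 rose and 2308 fell, or 31.5% of those tested. With median scaling the balance turned, with 1524 up and 2816 down. KLHL24 rose 12.7-fold, to -1.09 ± 0.28 (adjusted p = 5.86e-09), GPNMB, a lysosomal membrane glycoprotein, rose 16.3-fold. KRT13, above background on 1 of 4 control arrays, reached -2.40 ± 0.31 from -5.95 ± 0.60 (adjusted p = 1.17e-06). E2F1 at chromosome 20, 32263989 to 32264048, fell from 1.39 ± 0.11 in control to -1.31 ± 0.33, which is 6.52-fold, and its relative E2F2 fell 7.90-fold. UHRF1, which maintains DNA methylation at replication, fell 6.77-fold and FAM111B, a protease of dividing cells, 10.1-fold. CDC6 was at -6.81 ± 0.45, at least 3.7-fold lower. GAL, the neuropeptide galanin, fell 9.87-fold and TUBA4A, an alpha tubulin, 8.52-fold (adjusted p = 4.61e-09). A total of 1648 genes changed at least 2-fold, and with slide as a block 3894 genes passed.

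All 43 DNA replication genes fell with the combined treatment, also 43 adjusted over the list alone. Their median was -1.80 (adjusted p = 2.02e-32; 0.0173 with an estimated correlation), with -1.70 and -1.77 within slides and -1.65 and -2.01 within number pairs. Mitosis genes had 25 of 35 down, or 28 adjusted over the list alone, among them the mitotic kinase AURKB at -1.36 ± 0.21, with a median of -0.72 (adjusted p = 2.7e-10; adjusted p = 0.204 with an estimated correlation). FOXO targets had 19 of 25 up, or 20 adjusted over the list alone, with a median of 1.08 (adjusted p = 2.29e-09; 0.0173 with an estimated correlation), such as PIK3IP1, an inhibitor of PI3K, at 2.42 ± 0.27 with 2 of 4 control arrays above background. The p53 targets had 14 of 22 up, or 15 adjusted over the list alone (median 0.69, adjusted p = 5.41e-06; 0.00705 with an estimated correlation), with BBC3 at 2.15 ± 0.22. Ribosome biogenesis had 15 of 29 down and 1 up, or 16 and 1 adjusted over the list alone (median -0.38, adjusted p = 6.45e-06; 0.0136 with an estimated correlation), with NOP16, a nucleolar protein, at -1.10 ± 0.11. ER targets had 19 of 45 down and 4 up, also 19 and 4 adjusted over the list alone. Their median was -0.45 (adjusted p = 0.000407; 0.00899 with an estimated correlation), with -0.62 and -0.38 within slides and -0.50 and -0.42 within number pairs. PGR was at -1.17 ± 0.22 (adjusted p = 0.000804), GREB1 at -1.35 ± 0.30 (adjusted p = 0.00268), and TFF1 at -0.76 ± 0.15 (adjusted p = 0.00105). CCND1 was at -0.66 ± 0.15 (adjusted p = 0.00384) and PTEN, the PI3K-opposing phosphatase, at 0.71 ± 0.14 (adjusted p = 0.00145). ESR1 was at 0.33 ± 0.11 (adjusted p = 0.0379), a call that ended without control 1 (0.114), control 3 (0.0713), control 4 (0.058), combined 1 (0.0606), combined 3 (0.1) or combined 4 (0.0594). It ended too with median scaling (0.18, adjusted p = 0.484), the mean of its probes (0.193), slide as a block (0.136), only the groups compared (0.104), no filter (0.0999), array weights (0.0596) and position as a block (0.0557).

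Of the other lists that passed with the combined treatment, ATF4 targets had 13 of 33 up, or 16 up and 1 down adjusted over the list alone (median 0.76, adjusted p = 0.000407; adjusted p = 0.391 with an estimated correlation), with NUPR1 at 2.77 ± 0.29. NF-kB genes had 6 of 9 up and 1 down, or 8 and 1 adjusted over the list alone (median 1.10, adjusted p = 0.000804; adjusted p = 0.204 with an estimated correlation). MAPK genes had 7 of 26 up, also 7 adjusted over the list alone (0.35, adjusted p = 0.006; adjusted p = 0.254 with an estimated correlation). Heat shock genes had 8 of 14 down, or 11 adjusted over the list alone (-0.54, adjusted p = 0.000234; adjusted p = 0.0679 with an estimated correlation). Respiratory genes had 11 of 43 down, also 11 adjusted over the list alone (-0.32, adjusted p = 0.000109; adjusted p = 0.204 with an estimated correlation). Glycolysis had 9 of 21 down and 2 up, also 9 and 2 adjusted over the list alone (-0.38, adjusted p = 0.00423; adjusted p = 0.204 with an estimated correlation), with LDHA at -1.33 ± 0.12. A further 5 lists passed narrowly, each losing its call without some single array. Cell cycle inhibitors had 6 of 12 up and 2 down, or 8 and 2 adjusted over the list alone (0.69, adjusted p = 0.0305; adjusted p = 0.204 with an estimated correlation; 0.0798 without combined 1). Lysosomal genes had 10 of 34 up and 3 down, also 10 and 3 adjusted over the list alone (0.23, adjusted p = 0.0241; adjusted p = 0.204 with an estimated correlation; 0.057 without combined 1). Among them FLCN, which governs TFEB and its relatives, was at 1.59 ± 0.15 and GLA, alpha-galactosidase, at -1.86 ± 0.20. Fatty acid synthesis had 8 of 18 down and 2 up, or 9 and 2 adjusted over the list alone (-0.36, adjusted p = 0.0365; adjusted p = 0.23 with an estimated correlation; 0.0537 without control 1, 0.0502 without combined 3, 0.101 without combined 4, 0.0739 with slide as a block). ELOVL6, a fatty acid elongase, was at -1.48 ± 0.14. Apoptosis regulators had 10 of 22 up and 3 down, also 10 and 3 adjusted over the list alone (0.59, adjusted p = 0.0365; adjusted p = 0.105 with an estimated correlation; 0.0592 without control 3, 0.101 without combined 1). Luminal genes had 5 of 18 up and 1 down, also 5 and 1 adjusted over the list alone (0.26, adjusted p = 0.0365; adjusted p = 0.204 with an estimated correlation; 0.0517 without control 3, 0.0725 without combined 1, 0.101 without combined 4). ELF3, an epithelial transcription factor, was at 1.24 ± 0.17. All 34 list medians within slides and all 34 within number pairs kept the sign of the whole comparison. Median scaling moved the median change of all genes from 0.06 to -0.10. Under it MYC, at 0.66 ± 0.18 (adjusted p = 0.0121), and the receptor gene INSR, at 0.71 ± 0.18 (adjusted p = 0.00754), had adjusted p of 0.128 and 0.057. The MYC call ended too without both dim combined arrays (0.0838) and the INSR call with normexp correction (0.0522) and in the deposited table (0.056), and both ended on the arrays numbered 1 and 2 alone (0.464 and 0.0725).

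Combined treatment against tamoxifen alone asked how starved and fed cells differed when both had the drug. NUPR1 rose 10.8-fold (3.43 ± 0.29, adjusted p = 4.37e-06), ATF3 10.8-fold and KLHL24 5.23-fold, while CDC6 fell at least 2.41-fold and E2F1 4.47-fold. MAFF, a small MAF transcription factor, rose 5.98-fold, and CCL2, a monocyte chemokine, went from -6.77 ± 0.62 to -4.25 ± 0.21 (adjusted p = 1.06e-05). Of the 4 tamoxifen arrays 1 held CCL2 above background, and 3 each held MAFF and EGR3. EGR3 rose 4.85-fold and PGR 1.92-fold (0.94 ± 0.22, adjusted p = 0.00706). GREB1 was 2.08-fold higher (1.06 ± 0.30, adjusted p = 0.0202), a call that ended without tamoxifen 4 (0.0532), combined 3 (0.0561) or combined 4 (0.0561). A total of 3114 genes changed, 1630 up and 1484 down, or 20.1% of those tested. With slide as a block 1969 did, and with median scaling 807 rose and 1555 fell.

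DNA replication genes had 40 of 43 down, or 43 adjusted over the list alone. Their median was -1.55 (adjusted p = 1.01e-37; 0.0241 with an estimated correlation), with -1.55 and -1.59 within slides and -1.42 and -1.65 within number pairs. CCNE2, cyclin E2, was at -2.47 ± 0.24 and CDC45, a helicase factor, at -2.37 ± 0.35. Targets of p53 had 13 of 22 up, or 15 adjusted over the list alone (median 0.68, adjusted p = 2.35e-07; 0.00266 with an estimated correlation), with medians of 0.79 and 0.70 within slides. The call of each further list was lost with an estimated correlation. Mitosis genes had 20 of 35 down, or 24 adjusted over the list alone (-0.64, adjusted p = 1.12e-11; adjusted p = 0.157 with an estimated correlation), with CDK1, the mitotic kinase, at -0.88 ± 0.15. ATF4 targets had 19 of 33 up, also 19 adjusted over the list alone (0.91, adjusted p = 2.24e-08; adjusted p = 0.187 with an estimated correlation), with a median of 1.35 on the arrays numbered 1 and 2 and 0.53 on those numbered 3 and 4. FOXO targets had 12 of 25 up, or 13 adjusted over the list alone (0.60, adjusted p = 1.46e-05; adjusted p = 0.143 with an estimated correlation), with IRS2 at 1.63 ± 0.21. MAPK genes had 10 of 26 up, or 13 adjusted over the list alone (0.57, adjusted p = 5.98e-05; adjusted p = 0.143 with an estimated correlation). NF-kB genes had 7 of 9 up and 1 down, also 7 and 1 adjusted over the list alone (1.07, adjusted p = 0.000313; adjusted p = 0.143 with an estimated correlation). Respiratory genes had 5 of 43 down, or 2 adjusted over the list alone (-0.24, adjusted p = 3.8e-05; adjusted p = 0.157 with an estimated correlation). Heat shock genes had 3 of 14 down, or 4 adjusted over the list alone (-0.31, adjusted p = 0.00205; adjusted p = 0.143 with an estimated correlation). Fatty acid synthesis had 4 of 18 down, or 5 adjusted over the list alone (-0.34, adjusted p = 0.00394; adjusted p = 0.143 with an estimated correlation). Cholesterol synthesis had 4 of 23 down, or 5 down and 1 up adjusted over the list alone (-0.23, adjusted p = 0.0158; adjusted p = 0.404 with an estimated correlation). Glycolysis had 7 of 21 down and 1 up, or 8 and 2 adjusted over the list alone (-0.11, adjusted p = 0.0158; adjusted p = 0.244 with an estimated correlation). Lysosomal genes had 9 of 34 up and 2 down, also 9 and 2 adjusted over the list alone (0.16, adjusted p = 0.0303; adjusted p = 0.213 with an estimated correlation), with SQSTM1, an autophagy receptor, at 1.06 ± 0.15. Their call ended without tamoxifen 4 (0.0642), combined 1 (0.0922) or combined 4 (0.0647).

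ER targets had 14 of 45 members up and 4 down in the combined group against tamoxifen alone, or 14 and 5 adjusted over the list alone, and a median of 0.23, which did not pass (adjusted p = 0.054). The list passed without tamoxifen 1 (0.0247), tamoxifen 2 (0.0407), combined 2 (0.0324), combined 3 (0.0352) or combined 4 (0.0342). Apoptosis regulators had 7 of 22 up and 3 down and did not pass (0.43, adjusted p = 0.0628), but did without tamoxifen 1 (0.0394), combined 3 (0.0362) or combined 4 (0.0414). Basal genes, at 0.52 (adjusted p = 0.0764), passed without combined 4 (0.0319). ASNS was 2.03-fold higher (adjusted p = 0.0188), though not without tamoxifen 4 (0.0572) or combined 2 (0.0625), nor with slide as a block (0.0742). All 26 list medians within slides and all 26 within number pairs of the 13 lists that passed kept the sign of the whole comparison.

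Combined treatment against starvation alone asked what tamoxifen did in starved cells. ATP4A was at -7.63 ± 1.17 in starved cells and -1.92 ± 0.32 with the drug, at least 20.2-fold higher (adjusted p = 8.6e-06), and KRT13, above background on 1 of 4 starved arrays, rose from -6.02 ± 0.63 to -2.40 ± 0.31 (adjusted p = 1.14e-05). SPEG, a muscle-type kinase, rose 5.22-fold, SPINK4, a protease inhibitor of the gut, 5.02-fold, and RAPGEFL1, a relative of exchange factors for RAP proteins, 4.10-fold. SGK3 fell 2.87-fold (-1.52 ± 0.13, adjusted p = 1.14e-05), MGP 3.73-fold, ADAMTS9, a secreted protease, 3.67-fold, and ELOVL2, a fatty acid elongase, 2.27-fold. In total 199 genes changed, 100 up and 99 down, which is 1.28% of those tested, and 101 changed at least 2-fold. With median scaling 52 rose and 106 fell, and without both dim combined arrays 81 rose and 41 fell. No slide held both groups, so no within-slide value can be had: with slide as a block 22 genes passed, ATP4A, KRT13, SPEG, SPINK4, RAPGEFL1, SGK3, MGP, ADAMTS9 and ELOVL2 among them. The count was 28 with only the groups compared, 13 on the arrays numbered 1 and 2, 102 on those numbered 3 and 4, and 132 without starvation 2 or combined 2.

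ER targets fell in starved cells too: 7 of 45 members fell and 2 rose, or 16 and 2 adjusted over the list alone. Their median was -0.36 (adjusted p = 6.46e-09; 0.000257 with an estimated correlation), with -0.32 and -0.37 within number pairs and -0.35 with slide as a block. PGR was at -1.10 ± 0.22 (adjusted p = 0.0209; 0.0601 without starvation 1, 0.053 without starvation 2, 0.607 with slide as a block), and GREB1 at -1.11 ± 0.30 (adjusted p = 0.096, though 0.023 without combined 4 and 0.0266 with number pairs as a block). Ribosome biogenesis genes had 2 of 29 down, or 15 adjusted over the list alone (-0.38, adjusted p = 6.06e-14; 0.000344 with an estimated correlation), with medians of -0.32 and -0.37 within number pairs. DNA replication genes had 8 of 43 down, or 30 adjusted over the list alone (-0.60, adjusted p = 2.39e-29; 0.0383 with an estimated correlation). Their medians within number pairs were -0.80 and -0.37, and GINS1 was at -0.64 ± 0.11 (adjusted p = 0.0085; 0.533 with slide as a block). E2F1 was at -1.01 ± 0.24 (adjusted p = 0.0592, though 0.0268 without starvation 3, 0.0378 without starvation 4, 0.0356 without combined 1, 0.0337 with number pairs as a block and 0.0295 with position as a block). Mitosis genes had a median of -0.26 (adjusted p = 3.36e-07; adjusted p = 0.471 with an estimated correlation) with 0 of 35 called, also 0 adjusted over the list alone (limma), and BUB1B at -0.53 ± 0.15 (adjusted p = 0.118). Lysosomal genes had a median of 0.25 (adjusted p = 0.000889; adjusted p = 0.12 with an estimated correlation) with 0 of 34 called, or 4 up and 1 down adjusted over the list alone. FOXO targets had a median of 0.18 (adjusted p = 0.0015; adjusted p = 0.279 with an estimated correlation; 0.134 without starvation 1), with 2 of 25 up, or 4 adjusted over the list alone.

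The other 3 lists that passed between combined treatment and starvation depended on single arrays. ATF4 targets had a median of -0.25 (adjusted p = 9.79e-05; adjusted p = 0.471 with an estimated correlation; 0.157 without combined 3, 0.0502 without combined 4) with 0 of 33 called, also 0 adjusted over the list alone. Basal genes had 1 of 7 down, also 1 adjusted over the list alone, namely the caveola protein CAV1 at -1.10 ± 0.18 (adjusted p = 0.00461; 0.168 with slide as a block). The list's median was -0.08 (adjusted p = 0.0232; adjusted p = 0.12 with an estimated correlation; 0.0805 without starvation 2, 0.172 without combined 4). ER stress genes had a median of -0.14 (adjusted p = 0.0284; adjusted p = 0.471 with an estimated correlation; 0.126 without starvation 1, 0.384 without starvation 2, 0.233 without combined 3, 0.137 without combined 4, 0.217 with slide as a block), and 0 of 18 were called, also 0 adjusted over the list alone. Cholesterol synthesis, at 0.15, did not pass (adjusted p = 0.0607) but did without starvation 1 (0.00256), starvation 2 (0.000864), combined 2 (0.0365) or combined 3 (0.0187). The same held for MAPK genes, at -0.23 (adjusted p = 0.0567; 0.00256 without starvation 1, 0.012 without combined 3). It held for cell cycle inhibitors, at 0.18 (adjusted p = 0.117; 0.0437 without starvation 2, 0.0441 without combined 3), and for luminal genes, at 0.17 (adjusted p = 0.117; 0.0247 without combined 2). All 18 number-pair medians of the 9 lists that passed kept the sign of the whole comparison.

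**Figure D3:**
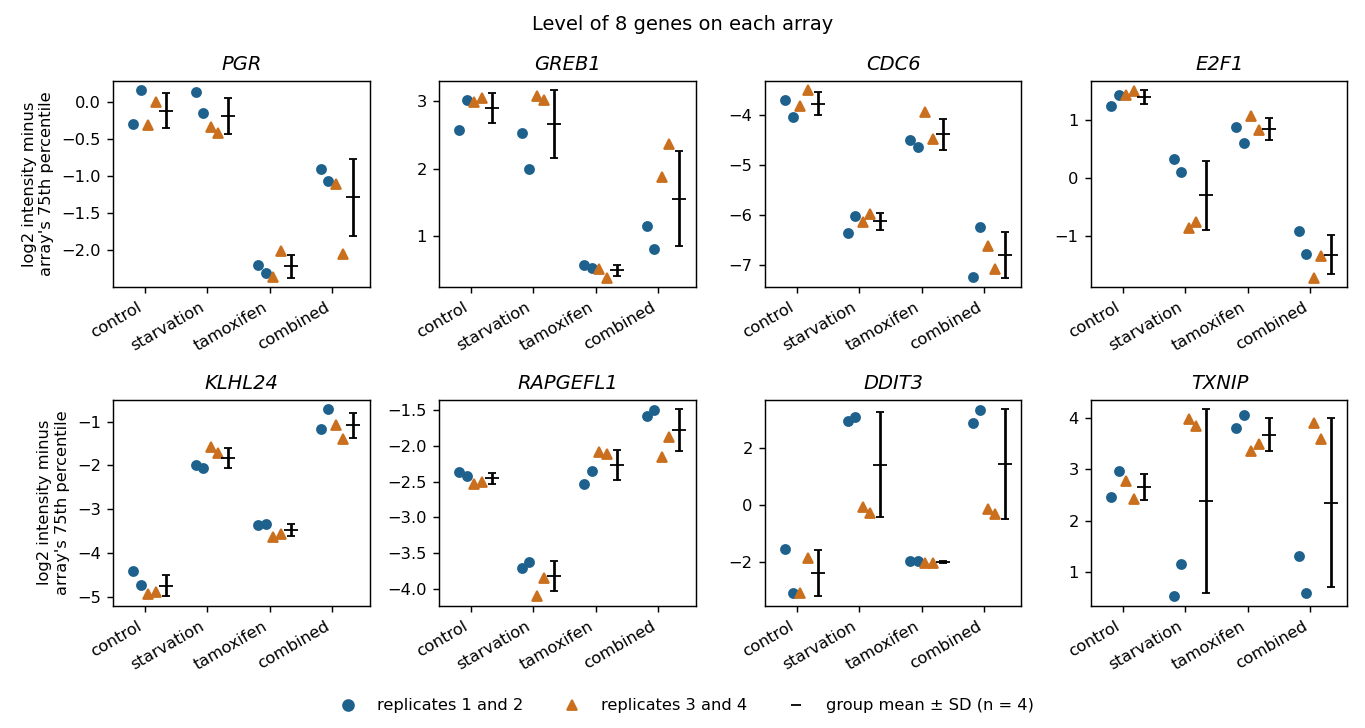
Log2 level of 8 genes on each of the 16 arrays, relative to the 75th percentile of the array, with the mean and standard deviation of each group of 4 (circles, arrays numbered 1 and 2; triangles, 3 and 4). PGR stands at -0.11 in control, -0.19 with starvation, -2.22 with tamoxifen and -1.28 with both, and TXNIP in starved cells splits by number.

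The interaction asked whether tamoxifen changed genes differently in starved and in fed cells. ER targets fell less in starved cells: the median difference of the tamoxifen effects was 0.38 (adjusted p = 2.6e-07; 0.000635 with an estimated correlation), above 0 in 37 of 45 members, and 0.38 and 0.40 within number pairs. GREB1 had an interaction of 1.30 ± 0.42 (adjusted p = 0.876), PGR of 1.01 ± 0.31 (adjusted p = 0.839), SGK3 of 0.72 ± 0.18 (adjusted p = 0.817) and IGFBP4, which binds insulin-like growth factors, of 1.04 ± 0.24 (adjusted p = 0.817). With limma 0 of 45 members passed alone, or 2 up adjusted over the list alone. A single gene of the 15529 passed, with 754 at an unadjusted p under 0.05. RAPGEFL1, at chromosome 17, 38351424 to 38351483, was at -2.45 ± 0.08 in control, -2.27 ± 0.21 with tamoxifen, -3.82 ± 0.21 with starvation and -1.78 ± 0.30 with both. Its interaction was 1.85 ± 0.22 (adjusted p = 0.00915). That call ended with median scaling (0.11), with normexp correction (0.0519), without both dim combined arrays (0.119) and with slide as a block (1.61, 0.788). Without combined 2 there were 3 genes.

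The DNA replication list had an interaction of -0.34 (adjusted p = 6.05e-09; adjusted p = 0.266 with an estimated correlation), with -0.54 and -0.17 within number pairs. FOXO targets stood at -0.32 (adjusted p = 0.00149; adjusted p = 0.266 with an estimated correlation). Mitosis genes stood at -0.13 (adjusted p = 0.00896; adjusted p = 0.728 with an estimated correlation; 0.0563 without control 1, 0.124 without starvation 1, 0.413 without starvation 2, 0.267 without combined 3, 0.253 without combined 4). Cell cycle inhibitors stood at -0.19 (adjusted p = 0.0351; adjusted p = 0.266 with an estimated correlation), and their call ended without control 3 (0.0945), control 4 (0.0708), starvation 2 (0.175), tamoxifen 1 (0.0871), tamoxifen 2 (0.0791), combined 2 (0.0745) or combined 3 (0.14). Heat shock genes stood at 0.18 (adjusted p = 0.0429; adjusted p = 0.266 with an estimated correlation), a call that ended without control 3 (0.0984), control 4 (0.152), starvation 1 (0.124), starvation 2 (0.0568), tamoxifen 1 (0.0919), combined 1 (0.1), combined 3 (0.0832) or combined 4 (0.0824). Lysosomal genes stood at 0.11 (adjusted p = 0.0429; adjusted p = 0.266 with an estimated correlation), with -0.01 and 0.27 within number pairs. Their call ended without control 1 (0.0503), control 2 (0.0645), control 4 (0.0708), starvation 1 (0.106), starvation 2 (0.0568), starvation 4 (0.0834), tamoxifen 3 (0.0649), tamoxifen 4 (0.105), combined 1 (0.168), combined 3 (0.0584) or combined 4 (0.142). In these 6 lists 0 members passed alone with limma, and 1 cell cycle inhibitor did adjusted over the list alone. Some lists gained a call without single arrays. Ribosome biogenesis stood at 0.10 (adjusted p = 0.0567; 0.0476 without control 1, 0.0438 without control 2, 0.0482 without control 3, 0.036 without starvation 3, 0.0324 without tamoxifen 4, 0.0362 without combined 3, 0.0321 without combined 4). Targets of p53 stood at -0.12 (adjusted p = 0.112; 0.049 without control 2, 0.0491 without tamoxifen 4) and ATF4 targets at -0.03 (adjusted p = 0.475; 0.0481 without starvation 3, 0.0324 without combined 1, 0.0101 without combined 2).

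The effects of each treatment with and without the other were compared across genes, which are not independent replicates. The share of all genes with the same sign was 77.7% for the starvation effect and 63.7% for the tamoxifen effect. The starvation effect without tamoxifen correlated with that under tamoxifen with r = 0.768 (jackknife standard error 0.085 over arrays, rho 0.726), and of the 3672 genes called without the drug 98.4% had the same sign under it. Genes called in both with 1 sign numbered 2246, against 198 up and 171 down if the calls were independent, and 3 had opposite signs. These effects share no arrays. Here and for the tamoxifen effect both tests use 1 estimate of each gene's spread, so the calls need not be independent. The tamoxifen effect in full medium correlated with that in starved cells with r = 0.47 (standard error 0.16, rho 0.395). A total of 116 genes, PGR, SGK3 and ATP4A among them, were called in both with the same sign, against 2.24 up and 1.61 down if independent, with 0 opposite. Starvation and tamoxifen effects against the shared control arrays correlated with r = 0.423, which is below the mean of 0.503 that 100 simulations of unchanged groups gave from the shared arrays alone. Their covariance was 0.0901, and 0.0413 in those simulations. With the controls split between the effects r was 0.266, from 0.217 to 0.312 over the splits. Of genes called in both, 198 rose with either treatment, KLHL24 and CCNG2 among them, 102 fell and 39 had opposite signs. Independent lists of these sizes would share 42.2 and 29, values that leave out the shared control arrays and so are not what unchanged groups would give.

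**Figure D4:**
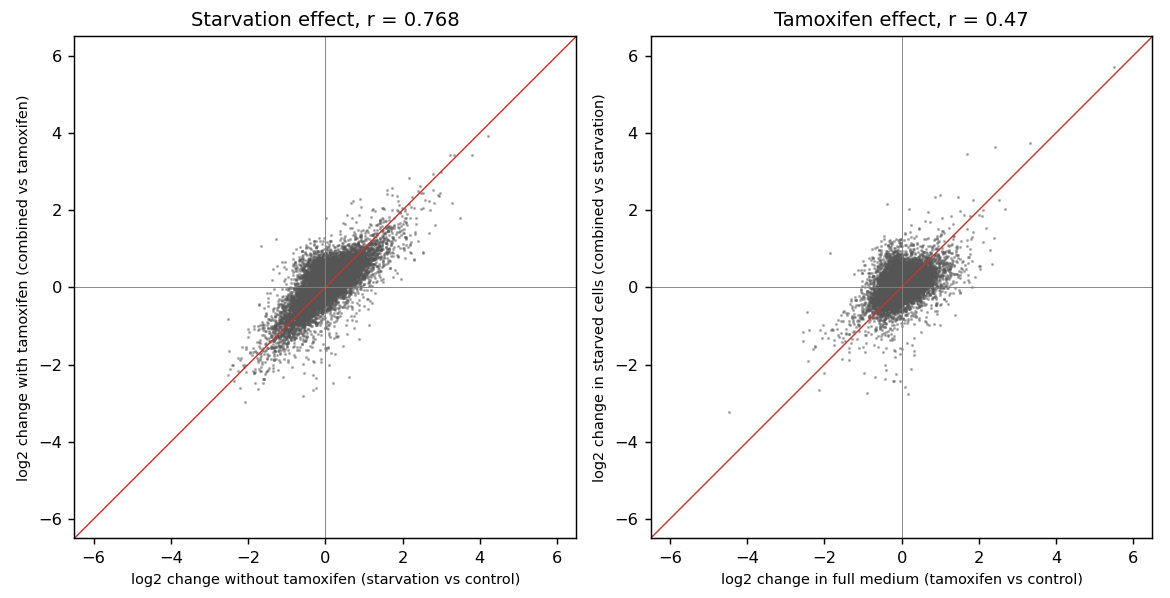
Log2 change of each of the 15529 genes, starvation effect under tamoxifen against starvation effect in full medium, and tamoxifen effect in starved cells against tamoxifen effect in full medium (1 point per gene; the line marks equal changes). The first pair of effects has r = 0.768 across genes and the second r = 0.47.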

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

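The tests of the difference between number pairs and of the slide block were chosen only after the results were seen, while the regroupings of each comparison and the tests of the ER target interaction were set out before.

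The starved arrays numbered 1 and 2 differed from those numbered 3 and 4 in 4300 genes, 1808 higher and 2492 lower, and 582 genes differed in their starvation effect between number pairs. A term for the number pairs over all 16 arrays called 1202 genes, as many as in 1 of 100 regroupings of each group into 2 and 2 arrays (the real one; highest other 1). That grouping was tested because it had stood out, so this count does not exclude chance. An offset between slides cancels from the difference, since each slide with starved arrays holds 1 array of each number pair. The difference also recurred within both slides that hold combined arrays, with slopes of 0.77 and 0.739 on that of starvation arrays. Both argue against slide. In control and tamoxifen arrays numbers 1 and 2 lie at positions 3 and 4, so 1 pair of values bears on array position (slopes of -0.0386 and -0.0453) and, with the sign turned, on a step shared by all arrays of a number pair (0.0386 and 0.0453): neither of these, alone and acting on all arrays alike, gives the difference. In combined arrays numbers 1 and 2 lie at positions 1 and 2, as in starvation arrays, and the slope was 0.755. A position effect in starved arrays alone, or effects of position and number that cancel in fed arrays, stay open. A biological candidate is a deeper shortage of glucose in the starved cultures numbered 1 and 2, which might raise glucose-regulated chaperones. The ER stress list was higher by 0.26 (adjusted p = 0.00492, or 0.0465 with an estimated correlation), with 6 of 18 members higher and 1 lower, under the limit of 0.3 set for it. In the starvation group alone it was higher by 0.34 (adjusted p = 0.00475, or 0.0359 with an estimated correlation). In the combined group alone it was higher by 0.27 (adjusted p = 0.0349, or 0.157 with an estimated correlation). HSPA5, the main glucose-regulated chaperone, went the other way (-0.34, adjusted p = 0.0457). TXNIP, which glucose raises, was lower (-2.94, adjusted p = 1.18e-05), as a shortage would give. Part of that gap, though, is a rise of TXNIP above control on the starvation arrays numbered 3 and 4. ATF4 targets, which rose with starvation, were higher (0.86), as a deeper shortage would give. DNA replication (0.38), mitosis (0.52) and cholesterol synthesis genes (0.48), which fell with starvation, were higher too, the opposite of a stronger starvation effect. The values thus point both ways, and this candidate stays open. A mix-up of labels or a different batch of medium was not tested.

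Between combined treatment and starvation 199 genes changed, and with slide as a block 22 did. An offset between slides would shrink the changes, but over the 199 genes the blocked changes had a slope of 0.97 (standard error 0.0071) on the others and 199 had the same sign. The standard errors grew by 1.49 times at the median, so lost precision is a candidate explanation: each group fills its own slides, and the block compares them only through control and tamoxifen arrays. Of the 35 splits of these 8 arrays 3 called at least as many genes, so this test cannot exclude chance for the count. Of the 199 genes 116 were also called with the same sign for tamoxifen in full medium, on other arrays, and 0 with the opposite sign. Independent calls would share 2.24 up and 1.61 down, but both comparisons use 1 estimate of each gene's spread, so their calls need not be independent. The signs, 116 the same and 0 opposite, argue against chance for the 116 genes. The split by number pair called 4058, several times the real count, which points to the structure described above, and starvation 1 with combined 2, 3 and 4 against the rest called 387. With the number pairs as a block 317 genes passed.

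ER targets fell less with tamoxifen in starved cells, by a median of 0.38 (adjusted p = 2.6e-07), above 0 in 37 of 45 members. The median was 0.37 with slide as a block, which argues against slide as the cause. It was 0.38 over the 41 members well above background on all 16 arrays, and 0.39 over the 39 members in no other list. The value thus stood in bright members and in members of no other list. Both checks left out few members, though, so these medians could hardly move and are weak tests of dim probes and overlap. A lower response to tamoxifen in starved cells is a hypothesis consistent with these values. What the medium itself held of oestrogens was not measured, and serum differed between the groups, so a change in the oestrogen supply is not excluded.

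In 4 comparisons under 5% of the splits called as many genes, the limit set before, which argues against a chance assignment of arrays to groups. With 35 splits 1 of 35 is the lowest share possible. The labels do not say that replicates were separate cultures, so these splits cannot exclude an accidental difference between cultures. The real split was the only 1 of 35 with so many genes for starvation against control (3672, highest other 1), tamoxifen against control (600, highest other 0), combined against control (4886, highest other 1) and combined against tamoxifen (3114, highest other 5). For the interaction the residuals were permuted, and the data themselves counted as 1 of 100 draws. Of these 3 called at least as many as the 1 gene of the data, a share under 5%, with a highest other of 569, which points to a structure of the samples. The call of that gene, RAPGEFL1, ended with median scaling (adjusted p = 0.11), normexp correction (0.0519), slide as a block (0.788) and without both dim combined arrays (0.119), so chance is not taken as excluded for it.

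Besides ER targets, the test of the difference itself picked out RAPGEFL1, with an interaction of 1.85, and 6 more lists, none of which kept its call with an estimated correlation (adjusted p from 0.266 to 0.728): DNA replication at -0.34, FOXO targets at -0.32, cell cycle inhibitors at -0.19, mitosis at -0.13, heat shock at 0.18 and lysosome at 0.11. The last 4 calls ended without single arrays, named in the report.

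Single arrays lay far from the other 3 of their group (by Dixon's test of the gap against the group's range) in 20 of 532 groups of 4 values, which is 3.76%. These groups came from 131 named genes and from 2 measures of each array, the 75th percentile and the share of spots above background; chance alone picks out about 1 in 20 groups. Combined 4 held 5 of them, with FSD1 at -2.26, CDKN1B at 0.61, MYBBP1A at -1.01, INSR at -2.01 and PIK3IP1 at -2.39. Combined 1 held FOXO3 at 2.77, IL20 at -6.21 and CDK1 at 2.03, and combined 2 MYC at 3.99. Control 2 held POLA2 at 1.23, HMGCS1 at 1.48 and UHRF1 at -0.63, control 1 GREB1 at 2.57, and control 3 SLC7A11 at -1.58. Starvation 1 held FSIP2 at -4.72 and ADAMTS9 at -1.26. Tamoxifen 2 held KIF11 at 1.37 and NEU1 at 2.45, and tamoxifen 4 FSD1 at -0.81 and AURKB at 0.75.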

How the results depend on the processing

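The number pairs as a block, each number pair alone and leaving out both dim combined arrays were chosen only after the data were seen. No list or named gene that was called reversed under any alternative run, and across the 6 comparisons the genes called both ways had the same sign except 3 with the mean of a gene's probes in combined against control. Of 204 calls among 259 named values, 181 were kept with slide as a block, 192 without both dim arrays, 129 on the arrays numbered 1 and 2, 176 on those numbered 3 and 4, and from 192 to 204 under the other alternatives fitted to all genes and arrays. Counts not given here stayed within 1.5 times the value reported, apart from single arrays left out, for which ranges and the arrays concerned stand below. Where a count moved, the cause was not tested unless the alternative holds fewer arrays, fewer genes or a stricter threshold by construction. The shared model had a median standard error of 0.201. With only the groups compared it was 0.138 for tamoxifen against control and 0.233 for combined against starvation. Fewer arrays thus do not account for the higher count in the former, and calls in the latter rest on a spread smaller than that of its own groups.

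The count for starvation against control was 3672, and it was 1281 on the arrays numbered 1 and 2, 2056 at an adjusted p under 0.01 and 1035 with a log2 change of at least 1. For tamoxifen against control it was 600, and 370 with median scaling, 283 with no filter, 2335 with array weights, 1639 with only the groups compared, 926 with number pairs as a block, 5 and 182 on the arrays numbered 1 and 2 and 3 and 4, 228 at 0.01 and 211 with a change of at least 1. For combined against control it was 4886, and 2642 on the arrays numbered 1 and 2, 3052 at 0.01 and 1648 with a change of at least 1. For combined against tamoxifen it was 3114, and 1969 with slide as a block, 1237 on the arrays numbered 1 and 2, 1546 at 0.01 and 808 with a change of at least 1. For combined against starvation it was 199, and 94 with no filter, 88 with array weights, 28 with only the groups compared, 22 with slide as a block, 317 with number pairs as a block, 13 and 102 on the arrays numbered 1 and 2 and 3 and 4, 122 without both dim arrays, 71 at 0.01 and 101 with a change of at least 1. For the interaction 1 gene passed; with limma it was 0 with median scaling, normexp correction, slide as a block, either number pair alone or without both dim arrays (754 at an unadjusted p under 0.05 as reported), and 2 with position as a block.

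With the replicate block, which takes the replicate number as a term, the counts were 3897, 651, 5181, 3261, 175 and 1 in the order above. Leaving out 1 array gave 2899 to 3667 genes for starvation against control, 300 to 496 for tamoxifen against control (300 without tamoxifen 1, 302 without tamoxifen 2, 310 without control 3, 329 without tamoxifen 4, 388 without control 4), 4101 to 5000 for combined against control, 2234 to 3408 for combined against tamoxifen, 132 to 241 for combined against starvation (132 without starvation 2 or combined 2) and 1 to 3 for the interaction (3 without combined 2).

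List calls numbered 64 over 27 lists and 6 comparisons, and 19 with an estimated correlation. The correlation of the starvation effects, 0.768, was 0.525 with no filter and 0.679 without both dim arrays, and that of the tamoxifen effects, 0.47, was 0.284 with no filter. Median scaling moved the median change of all genes from 0.06 to -0.10 for combined against control, from 0.07 to -0.05 for combined against tamoxifen and from 0.03 to -0.08 for combined against starvation, so with it changes there are to be read against those shifts. Signal over background sets a limit for ATP4A and, under combined treatment, CDC6, whose folds are bounds.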

Other observations

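The comparison of number pairs in starved cells was chosen only after the result was seen, and so were HSPA6, HMOX1, AREG, CYP1A1, VTCN1 and MAT2A, which are named here after their values were seen.

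The values below pool the starved arrays with and without tamoxifen. In starved arrays numbered 1 and 2 against those numbered 3 and 4, DDIT3 (the stress factor CHOP) was higher by 3.26 on the log2 scale, NIBAN1 by 3.57, HSPA6, an inducible chaperone above background on 3 of 4 starvation arrays, by 3.31, HMOX1, which degrades haem, by 2.43 and AREG, a ligand of the EGF receptor, by 2.40. The heat shock list, which does not hold HSPA6, did not pass there (median -0.24, 2 of 14 higher and 3 lower, camera adjusted p = 0.486). CYP1A1, a target of the aryl hydrocarbon receptor, had a difference of -4.28, TXNIP, which glucose raises, of -2.94 (adjusted p = 1.18e-05), VTCN1, an immune checkpoint protein, of -2.91 and MAT2A, which makes S-adenosylmethionine, of -2.79. Between the same numbers 33 genes differed over control and tamoxifen arrays pooled, against 4300 over the starved arrays. In control and tamoxifen arrays TXNIP differed by 0.11 and 0.52, DDIT3 by 0.15 and 0.07, AREG by 0.93 and 1.12, VTCN1 by 1.14 and 1.04, against its sign in starved arrays, and NIBAN1 by -0.62 and 0.50. Of the 4 control arrays 1 held NIBAN1 above background, so its difference there is between dim values.

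Over control and tamoxifen arrays pooled 9 lists differed between the same numbers, ATF4 targets (0.14, adjusted p = 2.39e-05; adjusted p = 0.053 with an estimated correlation) and, downward, DNA replication (-0.11, adjusted p = 0.00276; adjusted p = 0.226 with an estimated correlation) among them. None of the 9 kept its call with an estimated correlation.

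Among gene lists, ATF4 targets were higher in the starved arrays numbered 1 and 2, with a median of 0.86 (20 of 33 higher and 1 lower; adjusted p = 2.52e-12; 0.00331 with an estimated correlation). Mitosis genes were higher by 0.52 (20 of 35; adjusted p = 1.29e-11; 0.0465 with an estimated correlation) and cholesterol synthesis by 0.48 (12 of 23 higher and 3 lower; adjusted p = 0.000191; 0.0465 with an estimated correlation). The AHR list was lower, with a median of -0.75 (5 of 10; adjusted p = 0.00407; 0.0465 with an estimated correlation). DNA replication genes were higher by 0.38 (23 of 43 higher and 1 lower; adjusted p = 1.55e-08; adjusted p = 0.0599 with an estimated correlation) and NF-kB genes by 0.26 (adjusted p = 0.00492; adjusted p = 0.117 with an estimated correlation). In the combined group alone cholesterol synthesis (0.10, adjusted p = 0.114) and the AHR list (-0.40, adjusted p = 0.0844) did not pass. DNA replication (0.22, adjusted p = 0.00129; adjusted p = 0.248 with an estimated correlation), mitosis (0.47, adjusted p = 4.97e-10; adjusted p = 0.0709 with an estimated correlation) and NF-kB genes (0.40, adjusted p = 0.00265; adjusted p = 0.157 with an estimated correlation) lost their call there with an estimated correlation.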
